A study of Gallus gallus with 4 samples.

How the data were processed

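Gene expression was measured in 4 samples of chicken embryo on Agilent single-colour arrays, 2 samples of the indigenous Aseel breed and 2 of a control broiler line, all given in the labels as whole embryos of day 7. Per the labels' protocols, total RNA was extracted with Trizol and column purification, primed with oligo-dT, and turned into labelled cRNA with the dye Cy3. Per the file headers, each deposited scanner file holds intensity values made with Agilent Feature Extraction 10.7.3.1, where the processed signal is the spot's brightness after background subtraction and detrending within the array, with surrogate values for dim spots and no scaling between arrays. Mean spot intensity and local background intensity were also deposited, per the file headers. The authors' deposited value table holds log2 values, and what the authors did to make it is not given in the sources used here. Set against the scanner values, 99.5% to 99.6% of its values per array lay within 0.01 of log2 processed signal minus the array's 75th percentile, with no centring of genes, so its scale, centring and direction are known. The column medians of that table were -2.90, -2.93, -2.89 and -2.66 for Aseel 1, Aseel 2, broiler 1 and broiler 2.

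The design holds 57149 probes of 60 bases, control spots left out, on 61657 spots. A symbol in the files named 25938 probes. Of these, the accession of 10609 was found in a RefSeq table of the assembly GRCg7b, which gives another symbol for 1153, and the files' symbol was kept. Another 148 probes were named through their accession alone, and 31063 have no gene symbol here. In all 11566 genes had a probe. The array's grid was built on galGal3, and no genome was used, so probes were not mapped and no positions are given. Only the table's names were used.

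Signals were taken as log2 of the processed signal minus the array's 75th percentile. Control spots were left out, as were 35 probes with an outlier flag on any array, and the spots of a probe were averaged. Probes were tested if well above background, by the scanner's flag, on both arrays of at least 1 breed, which left 43588 probes of 10101 genes. Aseel was compared with broiler by limma's lmFit and eBayes without a block, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. A gene's value is that of its brightest probe over the 4 arrays. Where a gene was well above background on both arrays of a breed and on no array of the other, the fold is a bound. It sets the bright breed's mean against the dim breed's mean of, per array, the higher of the lowest signal well above background and the probe's own signal. No fold is given for a gene above background on 1 of the 2 arrays of its dim breed. The smallest p that an exact two-sided permutation test could give with 2 against 2 arrays is 0.333, so no such test was run on single values. All arrays lie on 1 slide from 1 scan, so neither could be tested as a batch. The 75th percentile of signal was 834, 681, 518 and 486 on Aseel 1, Aseel 2, broiler 1 and broiler 2, and the lowest signal well above background 2.82, 3.31, 2.97 and 4.93. A list's median did not move in any of the 40 lists when genes with a bound were set to it.

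Gene lists were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists. The 41 lists and all main settings were fixed before the data were examined, and 40 lists had the minimum of 5 measured genes. They cover skeletal muscle regulators, sarcomere, heart, growth hormone and IGF axis, thyroid axis, TGF-beta, activin and myostatin signalling, BMP signalling, WNT signalling, hedgehog, FGF and Notch signalling, cell cycle and DNA replication, apoptosis and p53, heat shock proteins and chaperones, innate immunity, cytokines, chemokines and their receptors, MHC and antigen presentation, white blood cells, red blood cells, liver, yolk sac and other extraembryonic, neurons, neural progenitors and glia, eye, cartilage and bone, collagens and extracellular matrix, blood vessel endothelium, skin, epithelium and feather, kidney and gonad, gut and lung, HOX genes, limb and craniofacial patterning, lipid synthesis and transport, cholesterol synthesis, glycolysis and gluconeogenesis, oxidative phosphorylation, cytosolic ribosomal proteins, proteasome, hypoxia response, immediate early genes and handling stress, antioxidant and oxidative stress and Z chromosome genes, and the W chromosome genes, which were too few to test. A gene can be in more than 1 list, as 79 were, and a whole embryo can express genes of all of them. Genes were named by a rule fixed in advance. It takes the 12 largest rises and 12 largest falls among genes past the threshold, above background on all 4 arrays and with no overlap of the breeds, up to 4 genes per breed above background in that breed alone, members of each list from the 4 with the smallest p-values, and MSTN, GHR, IGF1, IGF2, IGF1R, GAPDH and ACTB. AHSG, CPS1, COX8A and MYH15 were named after their values were seen, as the exceptions in their lists, and HINTW, SPINW, ATP5A1W and FAF were named as the W chromosome genes with tested probes.

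Camera tests whether a list's genes differ more than the other genes, whereas fry, among the alternatives, tests whether they change on balance. The other alternatives were quantile normalization, scaling on the array median, normexp background correction with an offset of 50, no filter on dim probes, a filter for all 4 arrays, an intensity trend in eBayes, the sample number as a block, the authors' value table, a threshold of 0.1, and leaving out each array in turn. Without 1 array the lone array was assumed to vary like the pair of the other breed. For lists, camera with an estimated correlation, the mean of all probes of a gene and 10000 random lists matched on signal were run. With random lists the p-value is two-sided against the matched lists, and the direction is that against the median of all tested genes. Scaling on the 5 brightest kinds of spike-in spots was added after seeing the data.

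The fit was tested on simulated data for Aseel minus broiler over 43588 probes. With 40 probes changed at each of 5 folds it called 0% at 2-fold, 0% at 4-fold, 75% at 8-fold, 75% at 16-fold and 100% at 64-fold, with 6 false calls, 5.66% of all calls. With 2000 at each it called 21.2%, 87.4%, 98%, 99.1% and 99.9%, with 342 false calls, 4.04% of all calls. In the list test on 10101 simulated genes, both lists shifted by 2-fold were called, and so was 1 of 38 unshifted lists. Simulated genes varied independently of each other, while the real lists had estimated correlations of up to 0.74 (cartilage and bone). The simulation therefore cannot give the rate of false list calls where genes of a list vary together. Analyses used R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.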

Results

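RNA of embryos labelled as whole and as 7 days old was compared between 2 kinds of chicken. Aseel is an indigenous, slow-growing breed that the submitters treated as the test group, and the control was a fast-growing broiler line. Each breed had 2 samples, and each sample was hybridised to 1 single-colour Agilent array of 57149 probes, with all 4 arrays on 1 slide. The arrays had 76.3% and 70.4% of probes well above background for Aseel 1 and 2 and 72.2% and 77.3% for broiler 1 and 2. No probe was saturated. With 2 arrays per breed, their number limits the precision of every value. The labels do not say that the samples came from separate embryos, so p-values measure only the spread between these samples, which may be technical.

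The series asks which genes are expressed at different levels in Aseel and broiler embryos. The arrays labelled Aseel carried far more muscle transcript than the broiler arrays: 34 of 42 measured sarcomere genes were higher, with a median log2 difference of 4.35. Genes of mitochondrial oxidative phosphorylation were also higher, 47 of 63. In the other direction, 23 of 34 liver genes, 23 of 33 limb and face patterning genes and 17 of 31 HOX genes and their cofactors were lower on the Aseel arrays, as were 26 of 46 cell cycle genes. In the main comparison no ribosomal protein gene passed the limma test in either direction (0 of 65, with 3 higher and 3 lower at an unadjusted p under 0.05), though some did with other settings. In what follows a gene's value is the log2 difference, Aseel minus broiler, ± its standard error (n = 2 arrays per breed), with the fold and the limma adjusted p. A fold given as "at least" is a bound for a gene not well above background on the arrays of 1 breed.

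Over the 43588 probes tested, 6985 were higher and 8360 lower in Aseel (limma, adjusted p under 0.05), which is 35.2% of them. By the brightest probe of each gene, 1367 of 10101 genes were higher and 2236 lower. A difference of at least 2-fold with no overlap of the breeds was found for 9803 probes upward and 11963 downward, against 20526 and 4540 with spike-in scaling and 6272 and 8539 with normexp background correction, which shrinks folds of dim probes. The breeds did not overlap at 74.9% of tested probes, and at 65.6% with no filter on dim probes, where chance gives 33.3%. The filter goes by breed, so it can raise the share. Pearson correlations across probes were 0.957 within Aseel, 0.957 within broiler and 0.758 to 0.822 between breeds. Probes are not independent replicates. The median SD between the arrays of a breed was 0.30 in Aseel and 0.27 in broiler, on the log2 scale.

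Fewer probes were called with any 1 array left out. Fewer arrays leave fewer degrees of freedom, so the fall alone does not show that the counts rest on particular arrays. It was much larger without Aseel 2 than without Aseel 1, however. Both fits hold as many arrays and take their spread from the broiler pair. The counts therefore depend on which Aseel array is kept. The direction of the calls depended on the scaling. Of the called probes, 45.5% were higher in Aseel with the 75th percentile as reference and 85.9% with spike-in scaling (14988 higher, 2461 lower), an alternative chosen after seeing the data, which moved the median of all probes by 1.10. All 23 gene lists called below had a median on the same side of 0 under spike-in scaling. The calls of all 23 lists came from camera with a preset correlation between genes, and none of the 40 lists tested passed with an estimated correlation (lowest adjusted p = 0.585, 0 lists at an unadjusted p under 0.05), while fry called 11. For 22 of the 23, the estimated correlation gave the highest adjusted p of all alternatives. With 2 arrays per breed that form of the test has few degrees of freedom, so it can call few lists.

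**Figure D1:**
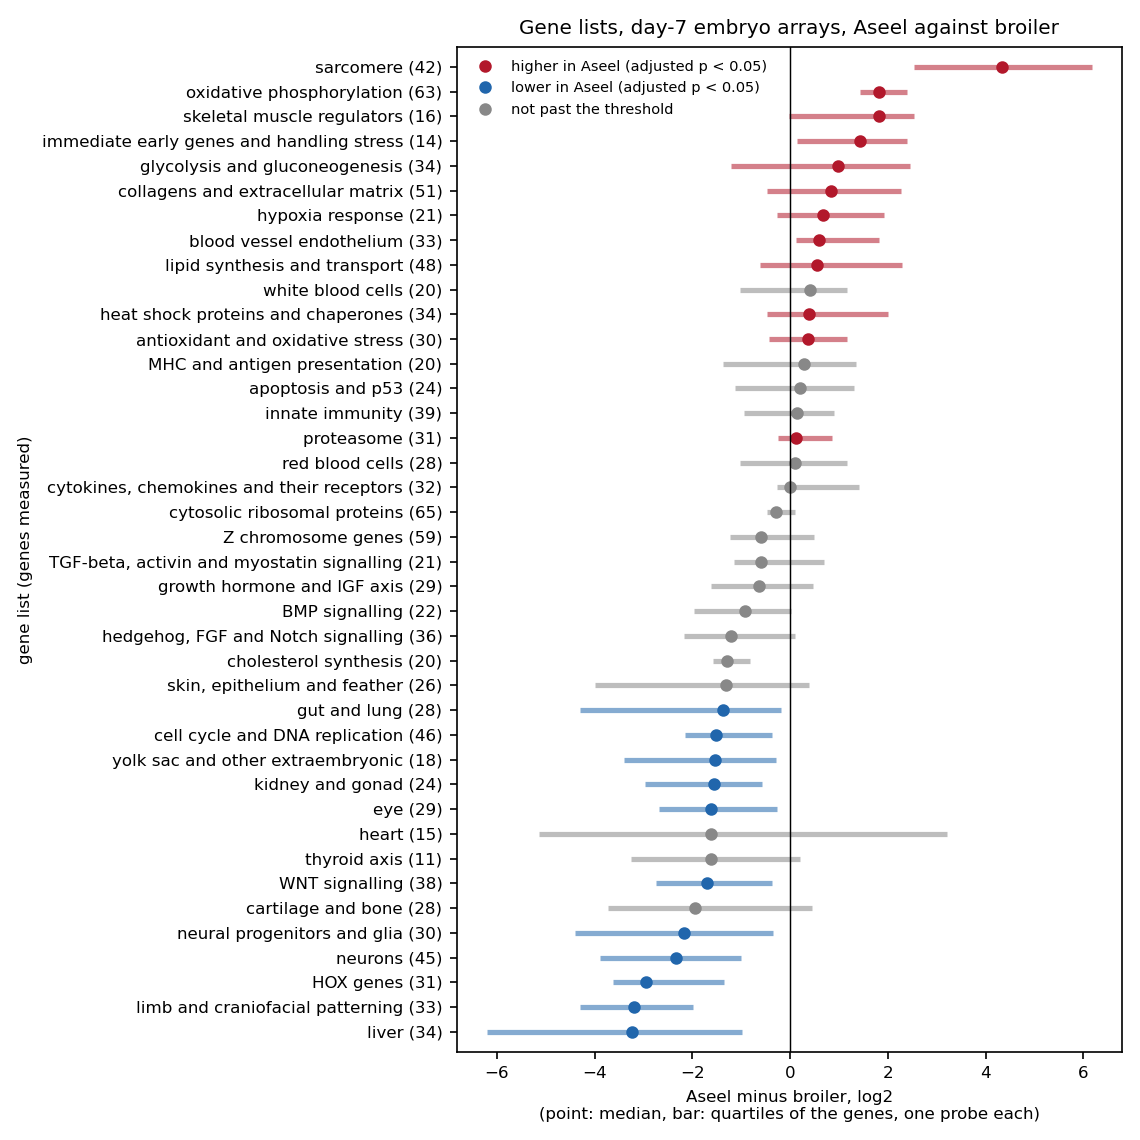
Median log2 difference, Aseel minus broiler, of each of the 40 gene lists (points), with the quartiles of its genes (bars) and the number of genes measured in brackets. Red lists were called higher and blue lists lower by camera with the preset correlation, and the medians run from 4.35 for the sarcomere to -3.23 for the liver.

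Sarcomere genes had the highest median of the 40 lists. Sarcomere genes encode the contractile filaments, and of the 42 measured, 34 were higher in Aseel, 1 was lower and 7 did not pass the test (34 higher and 1 lower when adjusted over the list alone). Skeletal muscle actin and fast troponin were among them, ACTA1 (9.36 ± 0.33, 656-fold, adjusted p = 0.00618), MYBPC1 (6.29 ± 0.30, 78.3-fold, adjusted p = 0.00618) and TNNI2 (6.42 ± 0.37, 85.4-fold, adjusted p = 0.00618). The Z-disc gene MYOZ1 (at least 1038-fold, adjusted p = 0.00618) was not well above background on the broiler arrays. The 1 that was lower was MYH15 (-4.64 ± 0.78, adjusted p = 0.0161), a myosin of the ventricle. As a list the sarcomere shifted higher (camera adjusted p = 3.26e-16, adjusted p = 0.585 with an estimated correlation, alternatives 1.44e-23 to 0.585). It held 4.07% and 4.34% of all signal on the Aseel arrays and 0.394% and 0.225% on the broiler arrays. Probes of myosin and actin families can bind more than 1 member.

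The 12 largest rises among genes above background on all 4 arrays included 4 genes of the fixed sarcomere and heart lists (ACTA1, CSRP3, MYH6 and PLN). They were led by CKMT2 (9.93 ± 0.54, 973-fold, adjusted p = 0.00618), the mitochondrial creatine kinase of muscle, then ACTA1. Genes of calcium handling in the sarcoplasmic reticulum followed, PLN (9.25 ± 1.15, 607-fold, adjusted p = 0.00976), TRDN (8.42 ± 0.56, 341-fold, adjusted p = 0.00634) and SRL (8.01 ± 0.58, 259-fold, adjusted p = 0.00634). The contractile and cytoskeletal genes MYH6 (9.08 ± 0.54, 540-fold, adjusted p = 0.00618) and SMPX (8.91 ± 1.07, 480-fold, adjusted p = 0.00941) were in the same range. Others were GATM (8.10 ± 0.34, 274-fold, adjusted p = 0.00618), which makes the precursor of creatine, ATP1B4 (7.98 ± 0.49, 252-fold, adjusted p = 0.00618) and DHRS7C (7.45 ± 0.54, 175-fold, adjusted p = 0.00634). The myelin gene MBP (8.26 ± 0.91, 306-fold, adjusted p = 0.00847) was also among them. CSRP3 (7.43 ± 1.69, 173-fold, adjusted p = 0.0301), a muscle LIM protein, completed the 12, but its call was lost without Aseel 1 (adjusted p = 0.0882) and without Aseel 2 (adjusted p = 0.0949).

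Regulators of skeletal muscle formed a separate list. Among its 16 measured genes, 8 were higher in Aseel, 2 were lower and 6 did not pass the test (9 higher and 2 lower when adjusted over the list alone). The transcription factor SRF (4.06 ± 0.36, 16.7-fold, adjusted p = 0.00686), the methyltransferase SMYD1 (4.17 ± 0.53, 18-fold, adjusted p = 0.00991) and the growth inhibitor MSTN (3.07 ± 0.47, 8.39-fold, adjusted p = 0.0133) were higher, and all 4 probes of MSTN were called. The list shifted higher (camera adjusted p = 0.00434, adjusted p = 0.618 with an estimated correlation, alternatives 0.000667 to 0.618), and fry did not call it (adjusted p = 0.0934).

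The list of mitochondrial ATP synthesis shifted higher on the arrays where sarcomere genes held 4.07% and 4.34% of the signal. Of 63 genes of oxidative phosphorylation, which make ATP in mitochondria, 47 were higher in Aseel, 1 was lower and 15 did not pass the test (53 higher and 1 lower when adjusted over the list alone). Examples came from several complexes, SDHA (3.33 ± 0.37, 10.1-fold, adjusted p = 0.00837), NDUFB8 (3.86 ± 0.43, 14.5-fold, adjusted p = 0.00844) and ATP5B (3.39 ± 0.41, 10.5-fold, adjusted p = 0.00943). The 1 lower gene was COX8A (-1.89 ± 0.36, adjusted p = 0.0205). The list median was 1.83 (camera adjusted p = 8.61e-17, adjusted p = 0.618 with an estimated correlation, alternatives 7.20e-22 to 0.618), and fry missed the threshold (adjusted p = 0.0644).

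Glycolysis and gluconeogenesis moved both ways. Of its 34 measured genes, 15 were higher in Aseel, 7 were lower and 12 did not pass the test (17 higher and 8 lower when adjusted over the list alone). The muscle phosphofructokinase and a kinase that slows pyruvate oxidation were higher, PFKM (6.93 ± 0.42, 122-fold, adjusted p = 0.00618) and PDK4 (5.76 ± 0.37, 54.3-fold, adjusted p = 0.00618). The enzymes ALDOB (-6.88 ± 0.36, 118-fold, adjusted p = 0.00618) and FBP1 (-6.02 ± 0.36, 64.7-fold, adjusted p = 0.00618), both abundant in liver, were lower, and 8 of the list's genes also belonged to another list. The median was 0.98 (camera adjusted p = 0.00376, adjusted p = 0.585 with an estimated correlation, alternatives 0.000577 to 0.585), and the call was lost, with the adjusted p in brackets, with fry (0.0538) and with spike-in scaling (0.128).

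On the arrays with the sarcomere rise (list median 4.35) the lipid list also shifted higher. Among 48 genes of lipid synthesis and transport, 19 were higher in Aseel, 5 were lower and 24 did not pass the test (19 higher and 6 lower when adjusted over the list alone). Fatty acid uptake and binding genes were higher, FABP3 (4.70 ± 0.33, 25.9-fold, adjusted p = 0.00634) and CD36 (5.83 ± 0.46, 56.8-fold, adjusted p = 0.00655), as was ADIPOQ (adjusted p = 0.00618), the adipocyte hormone adiponectin, above background on 1 of the 2 broiler arrays. The lipoprotein gene APOB (at least 832-fold, adjusted p = 0.00618) was lower and not well above background in Aseel. The median was 0.55 (camera adjusted p = 0.0061, adjusted p = 0.585 with an estimated correlation, alternatives 0.00105 to 0.585), 11 of its genes also stood in another list, and spike-in scaling ended the call (adjusted p = 0.0661). Of 20 cholesterol synthesis genes, 1 was higher in Aseel, 2 were lower and 17 did not pass the test (1 higher and 1 lower when adjusted over the list alone), with the ketone body enzyme HMGCS2 (-8.38 ± 0.50, 333-fold, adjusted p = 0.00618) lower and the receptor LDLR (3.29 ± 0.29, 9.81-fold, adjusted p = 0.00686) higher. That list was not called (median -1.30, camera adjusted p = 0.0979), but it was called lower, with the adjusted p in brackets, with random lists (0.0075), with array median scaling (0.0411), with spike-in scaling (0.0232), without Aseel 1 (0.00295) and without broiler 1 (0.0464).

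The lists of connective tissue and vessel genes shifted higher on the arrays where sarcomere genes held 4.07% and 4.34% of the signal, against 0.394% and 0.225% in broiler. In the 51 measured genes of collagens and extracellular matrix, 17 were higher in Aseel, 4 were lower and 30 did not pass the test (18 higher and 6 lower when adjusted over the list alone). Basement membrane collagen and tenascin X were higher, COL4A2 (3.48 ± 0.31, 11.1-fold, adjusted p = 0.00686) and TNXB (5.50 ± 0.41, 45.2-fold, adjusted p = 0.00634), and fibrillin 2 was lower, FBN2 (-3.06 ± 0.30, 8.31-fold, adjusted p = 0.0076). This list had a median of 0.83 (camera adjusted p = 0.0011, adjusted p = 0.653 with an estimated correlation, alternatives 1.05e-06 to 0.653), and fry did not call it (adjusted p = 0.152). Of 33 genes of blood vessel endothelium, 10 were higher in Aseel, 1 was lower and 22 did not pass the test (14 higher and 2 lower when adjusted over the list alone). They included EMCN (3.42 ± 0.39, adjusted p = 0.00864) and CLDN5 (3.69 ± 0.46, 12.9-fold, adjusted p = 0.00989), both of endothelial cell membranes, and ANGPTL2 (3.38 ± 0.37, 10.4-fold, adjusted p = 0.00823). Its median was 0.60 (camera adjusted p = 0.00125, adjusted p = 0.585 with an estimated correlation, alternatives 0.000456 to 0.585).

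The list of genes that respond within minutes to handling shifted higher by camera with the preset correlation, on the arrays where the sarcomere list had a median of 4.35. Of the 14 immediate early genes measured, 7 were higher in Aseel, 1 was lower and 6 did not pass the test (7 higher and 1 lower when adjusted over the list alone). Examples were the phosphatase DUSP1 (2.97 ± 0.33, 7.81-fold, adjusted p = 0.00852) and the transcription factor EGR1 (2.49 ± 0.31, 5.62-fold, adjusted p = 0.00962). Also higher was ATF3 (adjusted p = 0.00987), above background on 1 of the 2 broiler arrays. The median was 1.43 (camera adjusted p = 0.00376, adjusted p = 0.585 with an estimated correlation, alternatives 0.00232 to 0.585). For 21 genes of the hypoxia response, 7 were higher in Aseel, 0 were lower and 14 did not pass the test (7 higher and 0 lower when adjusted over the list alone), with BNIP3 (3.44 ± 0.33, 10.9-fold, adjusted p = 0.00745), which acts in mitochondrial clearance, and LDHA (4.57 ± 0.58, 23.8-fold, adjusted p = 0.00989), the lactate dehydrogenase of muscle. The median was 0.68 (camera adjusted p = 0.00759, adjusted p = 0.585 with an estimated correlation, alternatives 0.0019 to 0.585), and 8 of its genes also stood in another list.

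Heat shock, antioxidant and proteasome lists shifted higher on the arrays where sarcomere genes held 4.07% and 4.34% of the signal, against 0.394% and 0.225% in broiler. Camera sets a list against the other genes, and over all 10101 genes 1367 were higher in Aseel and 2236 lower. Of 34 heat shock proteins and chaperones, 12 were higher in Aseel, 3 were lower and 19 did not pass the test (12 higher and 3 lower when adjusted over the list alone). The small heat shock genes HSPB8 (4.37 ± 0.35, 20.7-fold, adjusted p = 0.00655) and HSPB1 (4.47 ± 0.45, 22.1-fold, adjusted p = 0.00763) were higher, with HSPA2 (3.36 ± 0.32, 10.3-fold, adjusted p = 0.00727). This list's median was 0.38 (camera adjusted p = 0.00879, adjusted p = 0.585 with an estimated correlation, alternatives 0.00144 to 0.585). In 30 antioxidant genes, 8 were higher in Aseel, 1 was lower and 21 did not pass the test (5 higher and 0 lower when adjusted over the list alone), among them GPX3 (4.64 ± 0.35, 24.9-fold, adjusted p = 0.00634), a glutathione peroxidase, and SOD2 (2.93 ± 0.41, 7.6-fold, adjusted p = 0.0113), the mitochondrial superoxide dismutase. Their median was 0.38 (camera adjusted p = 0.0367, adjusted p = 0.585 with an estimated correlation, alternatives 0.00843 to 0.585). Among 31 proteasome genes, 5 were higher in Aseel, 2 were lower and 24 did not pass the test (5 higher and 2 lower when adjusted over the list alone), such as PSMA5 (2.37 ± 0.30, 5.17-fold, adjusted p = 0.00994), with a median of 0.13 (camera adjusted p = 0.0371, adjusted p = 0.618 with an estimated correlation, alternatives 0.00677 to 0.618). All 3 calls were lost under some alternatives, with the adjusted p in brackets. For heat shock this was with random lists (0.0731) and with quantile normalization (0.0636). For antioxidant genes it was with random lists (0.061), with quantile normalization (0.114), with probes above background on all 4 arrays (0.0529) and without broiler 2 (0.0653). The proteasome call was lost with fry (0.109), with the mean of all probes (0.0517), with random lists (0.371), with quantile normalization (0.388), with probes above background on all 4 arrays (0.0524), without Aseel 2 (0.101) and without broiler 2 (0.104).

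Liver genes had the lowest median of the 40 lists. Out of 34 measured, 2 were higher in Aseel, 23 were lower and 9 did not pass the test (2 higher and 25 lower when adjusted over the list alone). Plasma protein genes led the falls, AMBP (-8.43 ± 0.40, 344-fold, adjusted p = 0.00618) and FGB (-6.22 ± 0.52, 74.3-fold, adjusted p = 0.00659). Fibrinogen alpha and plasminogen were well above background on the broiler arrays alone, FGA (at least 793-fold, adjusted p = 0.00618) and PLG (at least 287-fold, adjusted p = 0.00618). The 2 that were higher, AHSG and CPS1, were not well above background on the broiler arrays (AHSG at least 192-fold, CPS1 at least 4.27-fold), and they are named because they were the exceptions. The list's median was -3.23 (camera adjusted p = 1.31e-05, adjusted p = 0.618 with an estimated correlation, alternatives 1.22e-12 to 0.618). On these arrays the sarcomere list held 4.07% and 4.34% of the signal, against 0.394% and 0.225% on the broiler arrays.

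The 12 largest falls among genes above background on all 4 arrays included 3 genes of the fixed liver list, AMBP, FGB and APOA4 (-6.14 ± 0.62, 70.4-fold, adjusted p = 0.00767), an apolipoprotein. The metabolic genes HMGCS2, ALDOB and FBP1 were also among them, with SPP2 (-6.22 ± 0.50, 74.7-fold, adjusted p = 0.00655). Embryonic globins fell as well, HBZ (-7.52 ± 0.67, 184-fold, adjusted p = 0.00686) and HBG1, now HBBR (-6.99 ± 0.33, 127-fold, adjusted p = 0.00618), and globin probes can bind related globins. Others were CRABP1 (-6.51 ± 0.51, 91-fold, adjusted p = 0.00645), which binds retinoic acid, and GSC (-6.13 ± 0.39, 70.2-fold, adjusted p = 0.00618), a homeobox gene. The last was RAB11FIP3 (-6.20 ± 0.47, 73.5-fold, adjusted p = 0.00634), of vesicle traffic.

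**Figure D2:**
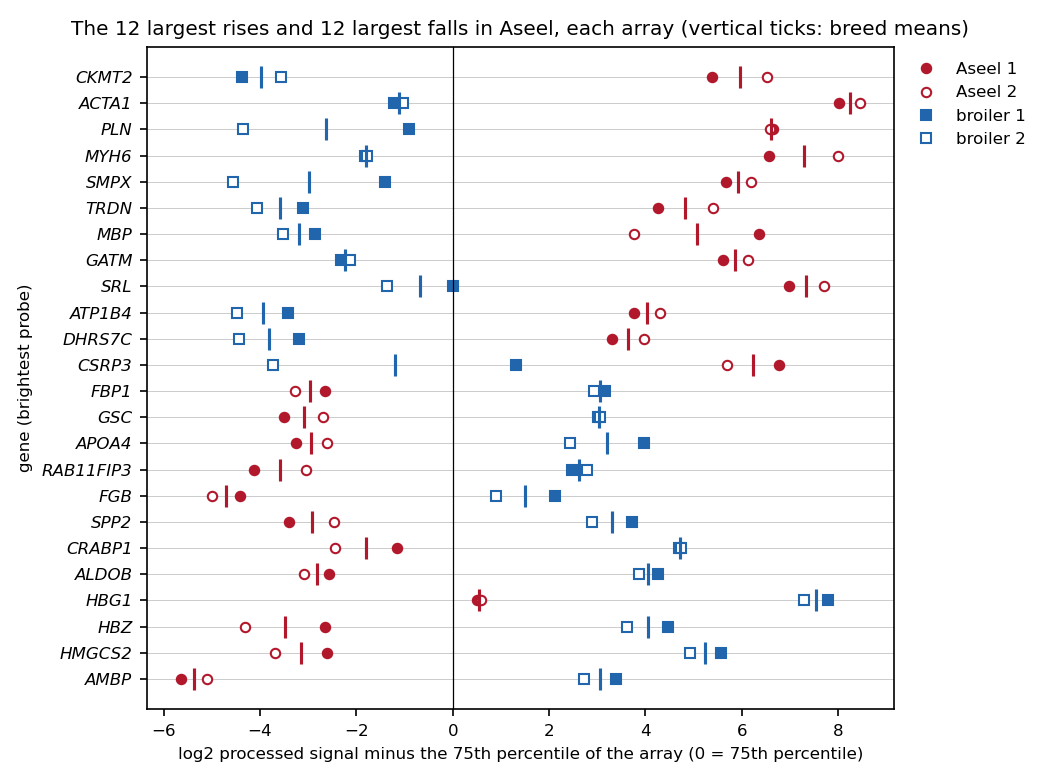
Log2 processed signal minus the array's 75th percentile (horizontal axis) on each of the 4 arrays for the 12 largest rises and 12 largest falls in Aseel. Circles are Aseel, squares broiler, filled for sample 1 and open for sample 2, and vertical ticks are breed means. CSRP3 is the gene whose broiler arrays lie farthest apart (SD 3.56).

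The lists of other inner organs also shifted lower, while 34 of 42 sarcomere genes were higher on the same arrays (median 4.35). Of 18 genes of yolk sac and other extraembryonic tissue, 0 were higher in Aseel, 7 were lower and 11 did not pass the test (0 higher and 8 lower when adjusted over the list alone). The plasma carrier TTR (at least 317-fold, adjusted p = 0.00618) and the egg white gene SERPINB14, now OVAL (at least 11.8-fold, adjusted p = 0.00719) were not well above background in Aseel. The median was -1.54 (camera adjusted p = 0.0152, adjusted p = 0.618 with an estimated correlation, alternatives 0.000579 to 0.78), and 12 of the 18 also stood in another list. For 28 gut and lung genes, 0 were higher in Aseel, 11 were lower and 17 did not pass the test (0 higher and 11 lower when adjusted over the list alone), led by INS (at least 200-fold, adjusted p = 0.00618), the insulin gene, and CDX2 (at least 72.7-fold, adjusted p = 0.00778), a regulator of the intestine. This median was -1.36 (camera adjusted p = 0.0257, adjusted p = 0.585 with an estimated correlation, alternatives 0.000907 to 0.585), with 11 shared genes. In 24 kidney and gonad genes, 1 was higher in Aseel, 12 were lower and 11 did not pass the test (1 higher and 13 lower when adjusted over the list alone), with LRP2 (at least 89.9-fold, adjusted p = 0.0091), the receptor megalin, and CDH6 (at least 15.8-fold, adjusted p = 0.00729) lower. Here the median was -1.57 (camera adjusted p = 0.00832, adjusted p = 0.585 with an estimated correlation, alternatives 0.000339 to 0.585), with 8 shared genes. Keeping only probes above background on all 4 arrays ended these 3 calls (adjusted p = 0.78, 0.298 and 0.0524). Quantile normalization ended the gut and lung call (adjusted p = 0.0777), and fry the yolk sac call (adjusted p = 0.0525).

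Lists of patterning genes of the early embryo shifted lower on the same Aseel arrays, on which sarcomere genes held 4.07% and 4.34% of the signal. Of 33 genes of limb and face patterning, 1 was higher in Aseel, 23 were lower and 9 did not pass the test (1 higher and 25 lower when adjusted over the list alone). They included PITX1 (-4.10 ± 0.29, 17.2-fold, adjusted p = 0.00634), of the hindlimb, and TBX5 (at least 86.9-fold, adjusted p = 0.00618), of the forelimb and heart, which was not well above background in Aseel. The list median was -3.19 (camera adjusted p = 1.45e-05, adjusted p = 0.585 with an estimated correlation, alternatives 4.76e-11 to 0.585). Of 31 HOX genes and their cofactors, 0 were higher in Aseel, 17 were lower and 14 did not pass the test (0 higher and 21 lower when adjusted over the list alone). The cofactor MEIS1 (-4.46 ± 0.47, 22-fold, adjusted p = 0.00792) and HOXA2 (-3.66 ± 0.48, 12.6-fold, adjusted p = 0.0104) were lower, and HOXD11 (at least 717-fold, adjusted p = 0.00618) was not well above background in Aseel. That median was -2.94 (camera adjusted p = 0.00046, adjusted p = 0.585 with an estimated correlation, alternatives 4.94e-09 to 0.585), and fry did not call it (adjusted p = 0.052).

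Among signalling lists, WNT was called lower, while 34 of 42 sarcomere genes were higher on the same arrays (median 4.35). Of its 38 genes, 1 was higher in Aseel, 17 were lower and 20 did not pass the test (1 higher and 22 lower when adjusted over the list alone). The inhibitor DKK2 (adjusted p = 0.00686), above background on 1 of the 2 Aseel arrays, and the ligand WNT7A (at least 6.78-fold, adjusted p = 0.00989) were lower. The median was -1.69 (camera adjusted p = 0.00866, adjusted p = 0.638 with an estimated correlation, alternatives 0.000667 to 0.638), and fry did not call it (adjusted p = 0.0697). Of 36 hedgehog, FGF and Notch genes, 7 were higher in Aseel, 13 were lower and 16 did not pass the test (7 higher and 18 lower when adjusted over the list alone), with FGF8 (-3.19 ± 0.30, 9.15-fold, adjusted p = 0.0071) and SHH (-3.97 ± 0.42, 15.6-fold, adjusted p = 0.00798) lower and FGF1 (2.84 ± 0.40, 7.16-fold, adjusted p = 0.0117) higher, and the list was not called (median -1.20, camera adjusted p = 0.161), except lower with random lists (adjusted p = 0.00978) and spike-in scaling (adjusted p = 0.0237). Of 22 BMP genes, 0 were higher in Aseel, 6 were lower and 16 did not pass the test (0 higher and 6 lower when adjusted over the list alone), and the list was not called (median -0.92, camera adjusted p = 0.247) except without Aseel 1 (adjusted p = 0.0314), and its median was 0.18 with spike-in scaling. The ligand BMP2 (-3.11 ± 0.52, adjusted p = 0.0155) lost its call without Aseel 2 (adjusted p = 0.0516) and without broiler 1 (adjusted p = 0.0595). For 21 genes of the TGF-beta and myostatin pathway, 3 were higher in Aseel, 5 were lower and 13 did not pass the test (3 higher and 6 lower when adjusted over the list alone), with the activin receptor ACVR2B (-2.55 ± 0.31, 5.86-fold, adjusted p = 0.0094) lower and the coreceptor TGFBR3 (at least 6.65-fold, adjusted p = 0.00821) higher, a call lost with normexp (0.15, adjusted p = 0.624). This list was not called (median -0.60, or 0.50 with spike-in scaling, camera adjusted p = 0.785).

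The lists of nervous system and eye genes shifted lower on the Aseel arrays, where the sarcomere list had its median of 4.35. Of 45 neuronal genes, 0 were higher in Aseel, 15 were lower and 30 did not pass the test (0 higher and 14 lower when adjusted over the list alone). Examples were GRIA2 (-4.85 ± 0.77, 28.8-fold, adjusted p = 0.0143), a glutamate receptor, and NHLH1 (at least 102-fold, adjusted p = 0.00656), a transcription factor of young neurons that was not well above background in Aseel. The median was -2.34 (camera adjusted p = 0.00367, adjusted p = 0.653 with an estimated correlation, alternatives 2.44e-06 to 0.653), and fry did not call it (adjusted p = 0.117). In 30 genes of neural progenitors and glia, 3 were higher in Aseel, 11 were lower and 16 did not pass the test (3 higher and 12 lower when adjusted over the list alone). The filament gene NES (-2.78 ± 0.32, 6.85-fold, adjusted p = 0.00878) and the proneural factor ASCL1 (-5.57 ± 0.79, 47.4-fold, adjusted p = 0.0117) were lower, while MBP was higher (8.26, adjusted p = 0.00847). Their median was -2.18 (camera adjusted p = 0.0392, adjusted p = 0.653 with an estimated correlation, alternatives 0.000173 to 0.653), and the call was lost, with the adjusted p in brackets, with fry (0.127), with quantile normalization (0.0549), with no filter on dim probes (0.0845), with probes above background on all 4 arrays (0.359), without Aseel 2 (0.108) and without broiler 2 (0.0616).

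For 29 eye genes, 1 was higher in Aseel, 9 were lower and 19 did not pass the test (1 higher and 9 lower when adjusted over the list alone). The pigment enzyme TYRP1 (at least 39.4-fold, adjusted p = 0.0066) and the retinal gene RLBP1 (-3.20 ± 0.39, 9.19-fold, adjusted p = 0.00953) were lower, and the lens crystallin CRYAB (2.66 ± 0.35, 6.33-fold, adjusted p = 0.0104), which muscle also makes, was higher. The eye list's median was -1.61 (camera adjusted p = 0.028, adjusted p = 0.653 with an estimated correlation, alternatives 1.03e-06 to 0.653). Its call was lost, with the adjusted p in brackets, with fry (0.118), with quantile normalization (0.0841), with probes above background on all 4 arrays (0.164), without Aseel 1 (0.0528), without Aseel 2 (0.0949) and without broiler 2 (0.117).

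The list of the cell cycle and DNA replication shifted lower on the Aseel arrays, where sarcomere genes held 4.07% and 4.34% of the signal against 0.394% and 0.225% in broiler. Of 46 measured, 0 were higher in Aseel, 26 were lower and 20 did not pass the test (1 higher and 27 lower when adjusted over the list alone). The replication factors GINS1 (-2.90 ± 0.32, 7.44-fold, adjusted p = 0.00849) and MCM3 (-3.01 ± 0.42, 8.06-fold, adjusted p = 0.0115) and the chromatin protein HMGB2 (-3.04 ± 0.36, 8.2-fold, adjusted p = 0.00939) were among the lowest p-values. The median was -1.51 (camera adjusted p = 0.000898, adjusted p = 0.618 with an estimated correlation, alternatives 0.000178 to 0.618), and fry missed the threshold (adjusted p = 0.0528). Of 24 genes of apoptosis and p53, 6 were higher in Aseel, 5 were lower and 13 did not pass the test (6 higher and 6 lower when adjusted over the list alone). The higher ones included CYCS (2.70 ± 0.34, 6.51-fold, adjusted p = 0.00989), cytochrome c, which the oxidative phosphorylation list also holds. The list was not called (median 0.20, camera adjusted p = 0.359), and its median ran from -0.10 to 0.30 with an array left out.

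Heart genes split. Of 15 measured, 6 were higher in Aseel, 7 were lower and 2 did not pass the test (6 higher and 7 lower when adjusted over the list alone), and the list was not called (median -1.62, camera adjusted p = 0.785). Contractile and calcium genes that skeletal muscle can share were higher, MYH6 (adjusted p = 0.00618) and PLN (adjusted p = 0.00976). The cardiac transcription factors NKX2-5 (at least 292-fold, adjusted p = 0.00634), IRX4 (at least 241-fold, adjusted p = 0.00634) and TBX5 (adjusted p = 0.00618) were not well above background on the Aseel arrays. Among probes above background on all 4 arrays the same list was called higher (median 3.15, adjusted p = 0.0334), and it was called lower with spike-in scaling (adjusted p = 0.038) and random lists (adjusted p = 0.0247).

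The growth hormone and IGF axis, of interest because the breeds differ in growth rate, was not called (median -0.64, or 0.46 with spike-in scaling, camera adjusted p = 0.785). Of 29 measured genes, 4 were higher in Aseel, 8 were lower and 17 did not pass the test (4 higher and 8 lower when adjusted over the list alone). The growth hormone receptor was higher, GHR (2.62 ± 0.33, 6.14-fold, adjusted p = 0.01), with all 8 of its probes called. IGFBP7 (3.72 ± 0.32, 13.1-fold, adjusted p = 0.00672), which binds IGFs, and SOCS3 (2.46 ± 0.29, 5.52-fold, adjusted p = 0.00934), a brake on cytokine signalling, were also higher. On the same arrays the sarcomere list had a median of 4.35, so breed and muscle content cannot be told apart for these genes. Differences of IGF1R (-0.89 ± 0.33, adjusted p = 0.0964) and IGF2 (-0.79 ± 0.44, adjusted p = 0.217) did not pass the test, and both lay above 0 with spike-in scaling (0.21 and 0.31). IGF1R was called lower with normexp (-0.83, adjusted p = 0.0433) and by 2 of its 7 probes in the main comparison, with none called higher. None of the 4 IGF2 probes was called, and their median was 0.42, on the other side of 0 from the brightest probe. IGF1 was not tested, since its 1 probe was well above background on 1 array. Of 11 thyroid axis genes, 2 were higher in Aseel, 4 were lower and 5 did not pass the test (2 higher and 4 lower when adjusted over the list alone), with TTR and DIO1 (adjusted p = 0.00719), a deiodinase above background on 1 Aseel array, lower. This list was not called (median -1.63, camera adjusted p = 0.396), except lower with spike-in scaling (adjusted p = 0.038).

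None of the immune and blood lists was called in the main comparison. Of 39 innate immunity genes, 7 were higher in Aseel, 8 were lower and 24 did not pass the test (7 higher and 8 lower when adjusted over the list alone), with a median of 0.15, a mean of -0.04 and a camera adjusted p = 0.393 toward higher (medians -0.21 to 0.06 with an array left out). Of 32 cytokine, chemokine and receptor genes, 8 were higher in Aseel, 3 were lower and 21 did not pass the test (9 higher and 3 lower when adjusted over the list alone), among them TNFRSF1A (2.55 ± 0.32, 5.85-fold, adjusted p = 0.01) and CXCR4 (at least 5.92-fold, adjusted p = 0.00802), whose call was lost with normexp (0.17, adjusted p = 0.604). Their median was -0.01, the mean 0.41 and the test pointed higher (camera adjusted p = 0.0825), and it passed without Aseel 1 (adjusted p = 0.0199), without Aseel 2 (adjusted p = 0.0377) and with quantile normalization (adjusted p = 0.0384). In 20 MHC and antigen presentation genes, 4 were higher in Aseel, 4 were lower and 12 did not pass the test (4 higher and 4 lower when adjusted over the list alone), with C4 (-2.70 ± 0.30, 6.51-fold, adjusted p = 0.00849) and B-LA (-2.46 ± 0.30, 5.51-fold, adjusted p = 0.00952) lower (median 0.29, camera adjusted p = 0.486, medians -0.48 to 0.51 with an array left out). Among 20 white blood cell genes, 5 were higher in Aseel, 4 were lower and 11 did not pass the test (6 higher and 4 lower when adjusted over the list alone), with BCL11A (-3.42 ± 0.31, adjusted p = 0.00707) lower and LECT2 (adjusted p = 0.0108), above background on 1 of the 2 broiler arrays, higher (median 0.40, camera adjusted p = 0.202), and the list was called higher without Aseel 2 (adjusted p = 0.00955). Of 28 red blood cell genes, 4 were higher in Aseel, 6 were lower and 18 did not pass the test (4 higher and 6 lower when adjusted over the list alone). The membrane skeleton genes ANK1 (5.19 ± 0.36, 36.6-fold, adjusted p = 0.00634) and TMOD1 (4.17 ± 0.33, 18-fold, adjusted p = 0.00655), which muscle also uses, were higher. The list's median was 0.10, its mean -0.11 and its camera adjusted p = 0.476 toward higher (medians -0.13 to 0.22 with an array left out), and it held 0.458% and 0.398% of signal in Aseel and 0.720% and 0.663% in broiler.

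Skeletal and surface tissues were not called as lists. Of 28 cartilage and bone genes, 3 were higher in Aseel, 4 were lower and 21 did not pass the test (3 higher and 3 lower when adjusted over the list alone). The matrix genes MATN2 (4.83 ± 0.36, 28.5-fold, adjusted p = 0.00634) and FMOD (4.94 ± 0.62, 30.7-fold, adjusted p = 0.00989) were higher and SOX5 (-3.95 ± 0.52, 15.4-fold, adjusted p = 0.0105) lower. The median was -1.94 (camera adjusted p = 0.778), and the list was called lower without Aseel 1 (median -3.60, adjusted p = 0.000609), with random lists (adjusted p = 0.000667) and with spike-in scaling (adjusted p = 0.0269). Of 26 skin, epithelium and feather genes, 3 were higher in Aseel, 9 were lower and 14 did not pass the test (3 higher and 12 lower when adjusted over the list alone), with the epithelial genes EPCAM (-5.39 ± 0.46, 42-fold, adjusted p = 0.0066) and KRT8 (-5.86 ± 0.60, 58-fold, adjusted p = 0.0078) lower. Its median was -1.32 (camera adjusted p = 0.142), and it was called lower, with the adjusted p in brackets, with the mean of all probes (0.0494), with random lists (0.0387), with array median scaling (0.0478), with normexp (0.0498), with spike-in scaling (0.00286), without Aseel 1 (0.00813) and without broiler 1 (0.0438). In the main comparison no ribosomal protein gene of 65 passed the limma test, also when adjusted over the list alone, with 3 higher and 3 lower at an unadjusted p under 0.05. The smallest p-values belonged to RPS10 (-1.19 ± 0.34, adjusted p = 0.0505) and RPL19 (1.05 ± 0.30, adjusted p = 0.0509). Both passed with normexp (adjusted p = 0.0419 and 0.019), with probes above background on all 4 arrays (0.0379 and 0.039) and with the intensity trend (0.018 and 0.0197), and RPL19 with spike-in scaling (0.0124). RPLP0 and RPL31 also passed with normexp (adjusted p = 0.0267 and 0.0407) and the intensity trend (0.0271 and 0.025), and RPLP0 with the array median (0.0402), probes above background on all 4 arrays (0.0457) and spike-in scaling (0.0193). The list's median was -0.28 (camera adjusted p = 0.788), and it was called higher with spike-in scaling (median 0.82, adjusted p = 0.0135). It also passed with random lists (adjusted p = 0.0468). There its direction, higher, was set against the median of all tested genes and not against the matched lists.

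The sex of the embryos is not in the labels, and in chickens females carry a W chromosome and males 2 Z chromosomes. Of 59 Z chromosome genes, 6 were higher in Aseel, 12 were lower and 41 did not pass the test (6 higher and 11 lower when adjusted over the list alone), and the list was not called (median -0.60, or 0.50 with spike-in scaling, camera adjusted p = 0.486). It shared 23 genes with other lists, ALDOB and GHR among them. The W chromosome list had too few measured genes for a test. All 8 probes of its gene HINTW were lower on broiler 2 than on the other 3 arrays, by 2.95 to 13.90 against broiler 1. On broiler 2, 3 of them stayed above the 75th percentile (0.93, 1.20 and 3.31) and 5 lay at -3.77 to -7.09. All 3 SPINW probes were also lowest on broiler 2, by 1.45, 2.42 and 7.47 against broiler 1. For both, no probe was called between the breeds. ATP5A1W, a gene with a close copy on the Z chromosome, was higher in Aseel by both probes (4.82, adjusted p = 0.00754, and 4.21, adjusted p = 0.0103), and these differed less between the broiler arrays (broiler 1 minus broiler 2 -0.45 and 0.75). FAF did not pass (-1.54, adjusted p = 0.128). It was lower on broiler 2 (-3.01) than on broiler 1 (-1.20), by 1.81, and lower still on both Aseel arrays (-3.62 and -3.66).

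Presence by the scanner's own flag separated the breeds further. There were 1391 probes well above background on both Aseel arrays and on neither broiler array, and 1671 the other way round. These 3062 became 6004 without Aseel 1, 4199 without Aseel 2, 4843 without broiler 1 and 5295 without broiler 2. In Aseel alone 196 genes were above background, led by MYOZ1, TXLNB (at least 395-fold, adjusted p = 0.00634), HNMT (at least 247-fold, adjusted p = 0.00618) and C1H7orf53 (at least 241-fold, adjusted p = 0.00618). In broiler alone there were 286, led by APOB, FGA, GKN2 (at least 738-fold, adjusted p = 0.00681) and HOXD11. TXLNB is a muscle protein and HNMT breaks down histamine.

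Common reference genes did not hold a single level. The brightest probe of GAPDH, a glycolytic enzyme, did not pass the test (0.22 ± 0.30, adjusted p = 0.585), but 4 of its 6 probes were called higher, by 2.26 to 4.03, and none lower. With spike-in scaling the brightest probe was called higher too (1.32, adjusted p = 0.047). The brightest probe of beta actin, ACTB, was lower (-1.52 ± 0.30, adjusted p = 0.0227). Of its 8 probes, 3 were called lower and 3 higher, the highest by 6.28, and its probes can bind other actins. The call on the brightest ACTB probe was lost without Aseel 2, broiler 1 or broiler 2 (adjusted p = 0.0957, 0.0924 and 0.0791) and with spike-in scaling (-0.42, adjusted p = 0.397).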

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

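The tests with spike-in scaling were chosen after seeing the data. No probe was called in opposite directions in the main comparison and any alternative. Among results on named genes, 1397 kept direction and side of the threshold with another setting, 22 were weaker, 20 stronger and 3 reversed, and with an array left out 598 kept both and 62 were weaker. For gene lists, 435 kept both with another setting, 55 were weaker, 16 stronger and 14 reversed, and 137, 8, 9 and 6 with an array left out. Counts of probes called stayed within 1.5 times of the main values with every planned setting that kept all 4 arrays, but normexp gave 6272 probes at least 2-fold higher without overlap, against 9803. Spike-in scaling gave 14988 higher and 2461 lower against 6985 and 8360, and 20526 and 4540 at least 2-fold apart against 9803 and 11963, since it moves all differences up by 1.10. Scaling on the array median moved the median difference by 0.15 and normexp by -0.12, against 0.06 for quantile normalization. Leaving out an array gave 2494 to 5863 probes higher, 2400 to 7033 lower and 4199 to 6004 above background in 1 breed, against 3062. Fewer arrays leave fewer degrees of freedom, and a flag on 1 array is met more easily than on 2. Degrees of freedom do not account for the gap in called probes between leaving out Aseel 1 and Aseel 2, since both fits hold as many arrays. The arrays' signal over background limits the rest, since 9032 probes were well above background on no array.

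The correlation of same-numbered samples' deviations was 0.0824, and the labels give them nothing in common but a number. The replicate block gave 6675 higher and 7362 lower and the same 12 and 11 lists. Slide and scan could not be run as a block, since all arrays share them. The number of lists called fell from 23 to 0 with an estimated correlation (0 of 40 lists at an unadjusted p under 0.05) and to 11 with fry, all 11 among the 23. Both take account of genes of a list varying together, and fry also sets a list against no change rather than against the other genes, so it differs from camera in 2 ways. An estimated correlation also makes camera test on the residual degrees of freedom, which are few with 2 arrays per breed. Called lists with an estimate below the preset 0.01 lost their calls too, with camera's unadjusted p in brackets. These were lipid (0.0644), hypoxia (0.0812), immediate early (0.0733) and antioxidant genes (0.128). Genes varying together do not explain those losses. The number of lists called was 17 to 28 with the other settings that kept all arrays. Apart from those 2 tests, lists lost calls in 20 combinations of list and setting with all arrays and in 8 with an array left out.

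The direction of list tests turned as follows, and the cause was not tested. The values are list medians, whose sign need not turn with the test. With fry these were innate immunity 0.15, MHC 0.29 and red blood cells 0.10. Ribosomal proteins turned with the mean of all probes (-0.14), random lists (-0.28), the array median (-0.14), normexp (-0.23) and spike-in scaling (0.82). With random lists the direction was set against the median of all tested genes, not against the matched lists. The heart list turned with normexp (-0.87) and with probes above background on all 4 arrays (3.15). That filter also turned the growth hormone and IGF axis (-0.43), thyroid axis (-0.0902) and cartilage (-0.82). Spike-in scaling turned MHC (1.39), IGF1R (0.21), IGF2 (0.31) and RPL31 (0.29). With an array left out, lists that turned ranged over -2.27 to -1.17 (heart), -0.91 to -0.20 (TGF-beta), -3.60 to -0.20 (cartilage) and -0.36 to -0.15 (ribosomal proteins). Z chromosome genes turned without broiler 2 alone, with a range of -0.77 (without broiler 1) to -0.39 (without broiler 2). Medians alone crossed 0 elsewhere. Spike-in scaling gave 0.46 for the growth hormone and IGF axis, 0.50 for TGF-beta, 0.18 for BMP signalling, 0.50 for Z chromosome genes and 1.09 for cytokines. With an array left out, medians ran from -0.48 to 0.51 for MHC, -0.21 to 0.06 for innate immunity, -0.13 to 0.22 for red blood cells, -0.10 to 0.30 for apoptosis and 0.05 to 0.44 for cytokines (main -0.01). Medians also crossed 0 for apoptosis, innate immunity and white blood cells with normexp, apoptosis with no filter, white blood cells with the filter for all 4 arrays, and cytokines with quantile normalization, the array median and the mean of all probes. With an array left out, some medians that stayed on 1 side of 0 moved widely. They ran from 0.16 to 0.86 for lipid synthesis and transport, 0.38 to 1.53 for collagens and 0.00805 to 1.10 for white blood cells. For the proteasome the range was 0.09 to 0.28, for skin -2.06 to -0.63 and for eye -2.62 to -0.93.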

Other observations

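The globin, defensin and cartilage genes of the first paragraphs, and the tests of scaling, of a later stage and of organ genes picked on 1 broiler array, were chosen after the result was seen. Globin genes did not move together. The primitive beta-type globin rho, HBG1 (now HBBR), stood at 0.51 and 0.59 on Aseel 1 and 2 and 7.78 and 7.30 on broiler 1 and 2, in log2 units over the array's 75th percentile. The primitive alpha-type globin pi, HBZ, was lower in Aseel by 184-fold (adjusted p = 0.00686), and HBE by 5.92-fold (adjusted p = 0.00895). The adult beta globin HBG2 (now HBBA) did not pass the test (0.05 ± 0.30, adjusted p = 0.916), nor did the alpha globin HBAA (now HBA1; brightest probe -0.51 ± 0.29, adjusted p = 0.225), although 1 of its 3 probes was called higher. Avian beta-defensins split as well: GAL9, now AvBD9, (at least 597-fold, adjusted p = 0.00618) and GAL10, now AvBD10, (-4.86 ± 0.65, 29-fold, adjusted p = 0.0109) were lower in Aseel (the GAL10 call was lost without Aseel 2, adjusted p = 0.0509), and GAL7, now AvBD7, (at least 52.4-fold, adjusted p = 0.00726) was higher. Spike-in scaling moves each of these differences up by 1.10, which puts that of HBAA above 0 and leaves the direction of the others. Related globins can bind the same probes.

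A few cartilage genes, picked after their values were seen, differed between the 2 Aseel arrays, while 7 of the 28 measured cartilage genes were called between the breeds. COL9A1 stood at 5.25 and -2.72 on Aseel 1 and 2 and 5.88 and 5.67 on broiler 1 and 2. MATN1 was at 0.50 on Aseel 1 and -7.69 on Aseel 2, HAPLN1 at 3.23 on Aseel 1 and -3.81 on Aseel 2, and COL9A2 at 2.88 on Aseel 1 and -4.25 on Aseel 2. Neurofilament NEFM also differed, with 2.70 on Aseel 1 and -7.25 on Aseel 2. None of these 5 genes passed the limma test between breeds (adjusted p = 0.226, 0.339, 0.218, 0.182 and 0.183), and the cartilage list median moved from -0.20 without Aseel 2 to -3.60 without Aseel 1.

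Muscle genes were high (ACTA1 at 8.02 and 8.45 on Aseel 1 and 2 and -1.22 and -1.02 on broiler 1 and 2) and genes of other organs low on the arrays labelled Aseel. The pooled median of 210 genes in 7 organ lists, at most -0.70 over 4 scalings, argues against scaling. In the main comparison the liver median was -3.23, with upper quartiles of -0.99 for liver and -0.99 for neurons. Under that scaling these values argue against a whole embryo of a later stage. Spike-in scaling moves each difference up by 1.10, which puts both upper quartiles above 0, so a later stage stays open there. The list medians stayed below 0 with it (-2.13 for liver and -1.24 for neurons). This test of stage used the liver and neuron lists alone. The primitive globin, early patterning and cell cycle genes, lower in Aseel as given above, were not part of it. An admixture of muscle RNA in up to equal parts predicts falls of no more than 1 on the log2 scale with spike-in scaling. The 63 organ genes bright in broiler argue against it (median -2.69, bootstrap interval -3.62 to -2.00). Genes picked on 1 broiler array and set against the other gave -2.62 and -2.14 (intervals -3.80 to -2.13 and -3.53 to -1.37). The median of all 210 (-0.70, interval -1.23 to -0.25) lies within the predicted range and does not decide. Of the 210, 97 fell by more than 1. Bootstrap intervals in this paragraph are over genes of the same 4 arrays, which are not independent, and do not measure the spread between samples. A candidate explanation that the tests leave open is RNA of a muscle-rich tissue: 19 organ genes outside the fixed lists had a median of -1.97 (-2.76 to -1.03, 0 higher, 10 lower) and 29 muscle genes outside them 2.69 (2.43 to 3.73, 24 higher, 1 lower, PVALB, whose 4 probes had a median of 0.38), or -0.87 and 3.79 with spike-in scaling. A difference between the breeds stays open too, untested, since all Aseel arrays carry it, as does a different age of the tissue.

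The 11 HINTW and SPINW probes were lower on broiler 2 than on the other 3 arrays, but 1 of 2 ATP5A1W probes was not (broiler 1 minus broiler 2 -0.45, and 0.75 for the other). ATP5A1W has a close copy on the Z chromosome, and whether its probes tell the copies apart was not tested. FAF fell by 1.81 from broiler 1 to broiler 2, but it was not lowest on broiler 2 (-3.01, against -3.62 and -3.66 in Aseel). A failure of that array would lower other bright probes, but 0.371% of 14278 were lower than on broiler 1 by more than 4, and 6 of those 53 were of HINTW or SPINW. If broiler 2 came from male and broiler 1 from female embryos, Z genes may be higher on broiler 2: the median over 59 Z genes was 0.39 (bootstrap interval 0.26 to 0.68, 45 higher) against -0.09 for all genes, and 0 of 10000 matched random lists came as high (one-sided permutation p = 1e-04, the smallest they can give, over genes and not samples, since it sets 1 array against 1). The breeds' embryos may then differ in the mix of sexes, which the labels do not give.

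Called probes made up 35.2% of those tested. If sequence differences of the breed under single probes made them, other probes of the same gene would follow by chance, in 50.9% of pairs. In 3866 pairs that share no stretch of 20 bases, 87.0% lay in the same direction as the called brightest probe. The 87.0% argues against that explanation for the calls as a whole, while a difference of tissue or of breed stays open.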
